A study of Mus musculus with 20 samples.

How the data were processed

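Gene expression was measured by RNA sequencing of liver from 20 individual female mice, 5 in each of 4 groups formed by diet (oral combined contraceptives or vehicle) and activity (voluntary wheel running or sedentary). Libraries were stranded and paired-end, per the labels' protocols. Reads were aligned to mm10 with STAR, and R 4.05 and limma were named, per the submitters' processing notes. The counting program, the annotation and the strand setting are not stated in the sources used here. The deposited values were taken to be expected counts per gene, not scaled between libraries, judged from the values. That unit rests only on 2 genes with values that were not whole, which were not used. Every value used was whole, so plain counts are not ruled out. Counts were rounded to whole numbers, which changed none of the values used. The planned design had assumed counts. Totals ran from 10883936 to 16134618 counts per library.

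The table held 35504 genes, of which 23993 (67.58%) had an intact line. The other 11511 (32.42%) were left out as displaced or doubtful. Of these 9824 held a 1 in the first library and 0 elsewhere, and 280 held text and 0 elsewhere. Another 570 held a 1 followed by counts moved right by 1 place, and 29 held text and counts moved by 2 places. The last were 806 that started with a 1 at a mean count of at most 10 and were left undecided, and 2 with values that were not whole. These genes were not used here, apart from the alternatives named below. For the 570 genes moved by 1 place, the mean log2 profile over libraries was correlated with the median profile of highly expressed intact genes, at 0.25 as they stood and 0.87 when moved back. Taken singly, 72.5% of them had a higher correlation when moved back. The same move applied to a sample of 408 highly expressed intact genes lowered the value from 0.98 to -0.11, and 8.8% of these were higher when moved. Of the intact genes 14236 had a count in any library. Among the IDs 35467 had a symbol and a position in GENCODE vM21 (GRCm38, the build that mm10 names), and 26 symbols had been turned into dates and were taken from the ID. Because displaced genes were left out, 16 of a fixed panel of 32 genes were tested, and each gene list is described by its tested members only.

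Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 10207 genes holding 99.95% of the counts, and libraries were scaled by TMM (factors 0.90 to 1.06 in vehicle libraries and 0.99 to 1.11 in OC libraries). A quasi-likelihood model with 1 mean per group was fitted to all 20 libraries (common biological coefficient of variation 0.178). It gave 7 contrasts: OC against vehicle in sedentary and in running mice, running against sedentary on each diet, both effects averaged over the other factor, and their interaction. P-values were adjusted by Benjamini-Hochberg over the 10207 genes, with a threshold of 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. Standard errors are those of the fitted log2 fold changes, folds are fitted folds, and CPM values are means with the standard deviation of 5 mice. A fold against a group with 0 counts is a lower bound that uses a floor of 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% interval.

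From knowledge of the field, 40 gene lists were fixed. Of these, 35 had at least 5 tested members and were tested. The lists of mitochondrially encoded, skeletal muscle, erythroid, pancreatic acinar and adipocyte genes had 0, 0, 1, 1 and 4 tested members and were not tested. Lists were tested against the other genes with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Counts of changed members are given over all genes and, where a list is described, also adjusted over the list alone.

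The genes named were chosen by a fixed rule. For each contrast it took called genes with a mean of at least 1 CPM, a symbol other than that of a predicted gene, and every library of the first group on 1 side of the mean of the other. From these came the 6 largest changes and the 3 smallest adjusted p in each direction, and up to 2 called members in each direction of each list described. The fixed panel and up to 3 uncalled members of a described list were given as values only. Part of these was left out for length, and some genes that the rule names are not reported here.

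The steps were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed. For OC in sedentary mice 29 of 58 changes of 1.5-fold, 79.2% of 2-fold and 95.7% of 4-fold changes were recovered among 10207 genes. For OC averaged over activity the shares were 75.8%, 90.5% and 100.0%, for running averaged over diet 74.2%, 93.9% and 100.0%, and for the interaction 21.9%, 60.6% and 96.4%. Unchanged genes made up 5 of 158 calls for OC in sedentary mice and 12 of 163 for running in vehicle mice. They made up 12 of 190 for OC averaged, 6 of 185 for running averaged and 5 of 118 for the interaction. A list raised 1.3-fold was called, and 0 other lists of 35 were. Genes were drawn independently, so this simulation cannot show how often correlated genes lead to list calls. Random regroupings of the real libraries, given below, often called lists.

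The groups, comparisons, tests, gene lists, rule for named genes and a first set of alternatives were fixed before the data were examined. That set was DESeq2 size factors, library totals alone, no filter, a stricter filter (1 CPM in 10 libraries), the DESeq2 1.42.0 Wald test, limma voom with and without sample weights, fits of the compared groups only, the other list tests, and leaving out each library in turn. After the data were seen 4 more were added. They were including the undecided genes, including the 570 moved genes moved back without the library they lose, using all lines as they stood, and leaving out 3 libraries with muscle transcripts.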

Results

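Liver RNA from 20 female mice was sequenced to ask what oral combined contraceptives (OC) in the diet and voluntary wheel running did to hepatic gene expression. The mice formed 4 groups of 5: vehicle diet and sedentary, vehicle diet and running, OC diet and sedentary, and OC diet and running. Each library came from the liver of 1 animal, so replicates were separate mice. Total counts over the genes used ran from 10883936 to 14260634 per library in sedentary vehicle mice, 13886098 to 16134618 in running vehicle mice, 12172401 to 14759028 in sedentary OC mice and 12769367 to 14757592 in running OC mice. After the filter on low counts 10207 genes were tested. The 13 mitochondrially encoded genes used were listed at 0 in every library, so only nuclear genes of the mitochondrion are described. Coordinates are from GENCODE vM21 on GRCm38 (mm10). The first principal component of log2 CPM (counts scaled to a common library total) held 39.2% of the variance and separated the diets, with scores of 21.5 to 30.0 in vehicle libraries and -36.0 to -14.8 in OC libraries. The second component held 11.6% and set apart replicate 2 of the sedentary vehicle group, at 53.0 against -17.1 to 11.2 in the other 19 libraries.

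**Figure D1:**
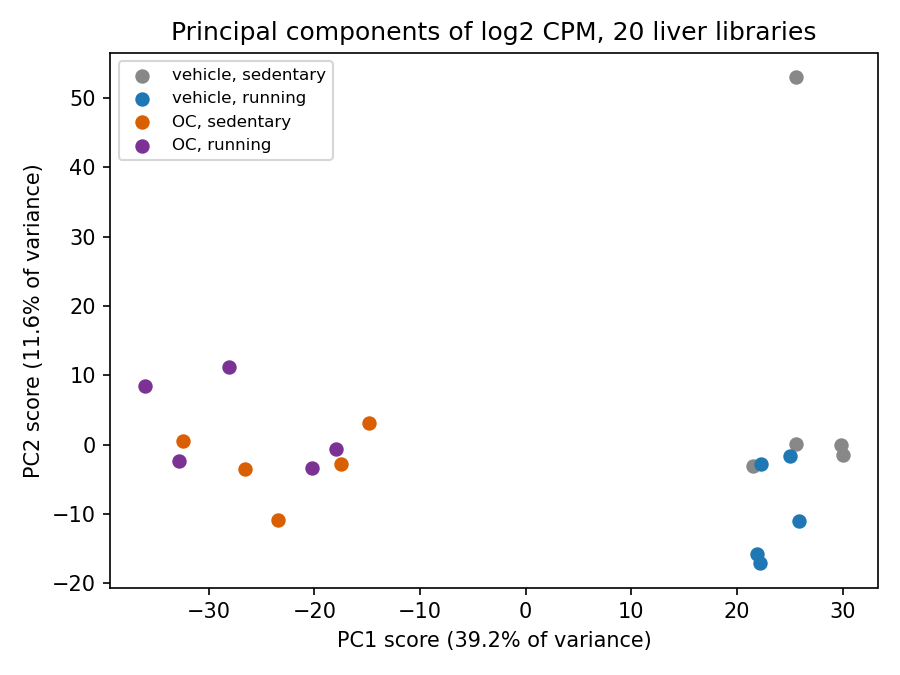
Scores of the 20 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, in arbitrary units, with 1 point per mouse coloured by group. The 10 OC libraries lie at -14.8 or below on the first component and the 10 vehicle libraries at 21.5 or above, while 1 sedentary vehicle library lies at 53.0 on the second.

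The first comparison asked what the contraceptive diet did in sedentary mice. Rgs7bp (chromosome 13, 104945904 to 105054930, minus strand), which encodes a binding partner of G-protein regulators, rose from 2.17 ± 0.511 CPM on vehicle to 78.3 ± 25.5 CPM on OC (SD, n = 5; log2 fold change 5.18, SE 0.31; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.34e-10). Lifr, the receptor for leukaemia inhibitory factor, rose from 280.7 ± 69.2 to 1704 ± 338.7 CPM (log2 fold change 2.60, SE 0.28, adjusted p = 3.05e-06). In all, 1665 genes (16.3% of those tested) passed the threshold, 930 higher and 735 lower on OC. Of these 354 changed more than 2-fold. Without OC sedentary replicate 1 the count was 998. With library totals as the only scaling the calls were 1712 higher and 360 lower (82.6% higher, against 55.9% with TMM), and the median of all genes then lay at 0.10 on the log2 scale.

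The increases in sedentary mice included Bmp7, a bone morphogenetic protein, at 23.4-fold, and Nebl, an actin-binding protein of the nebulin family, at 19.6-fold. Obp2a had 0 counts in the 5 vehicle libraries and 291 on OC, at least 85.7-fold higher against a floor of 3 counts over the group. Asic2, an acid-sensing ion channel, had 0 and 136 counts, at least 40.0-fold higher. Krt4 had 1 count on vehicle and 851 on OC, a ratio of 751.8 with a 95% counting interval of 134.6 to 29728. Its fitted log2 fold change was 8.94. Without sedentary vehicle replicate 5, which held that count, the vehicle group was at 0 and the fitted value of 10.42 was no measured fold. Such intervals and floors cover counting error only. The decreases included Hamp2, a hepcidin paralogue, from 769.7 ± 541.7 to 31.5 ± 5.28 CPM, Krt23 at 16.6-fold lower, Eci3, an enoyl-CoA isomerase, at 15.8-fold lower (log2 fold change -3.98, and -4.79 without OC sedentary replicate 5) and Ces1b, a carboxylesterase, at 4.55-fold lower. In the sedentary OC libraries Eci3 held only 0 to 0.388 CPM, so its fold is imprecise. Pnpla5 fell by 3.89 on the log2 scale (SE 1.22, adjusted p = 0.0341). The log2 fold change was -3.02 without sedentary vehicle replicate 5 and -4.62 without OC sedentary replicate 2. The call was lost in limma voom without and with sample weights (adjusted p = 0.199 and 0.377) and without sedentary vehicle replicate 3 or 5 (adjusted p = 0.0702 and 0.123) or OC sedentary replicate 1, 3, 4 or 5 (adjusted p = 0.0775, 0.0670, 0.0652 and 0.0565). The fall of Mmp12, from 12.1 ± 25.2 to 0.484 ± 0.268 CPM, rested on sedentary vehicle replicate 2: without it the log2 fold change was -0.72 and the adjusted p 0.439.

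In sedentary mice, of 27 tested genes of the male-biased list 21 rose, 0 fell and 6 did not pass, and 21 rose when adjusted over the list alone. The major urinary protein genes Mup15 and Mup17 rose from 2.19 ± 2.13 to 516.5 ± 677.4 CPM and from 2.54 ± 2.57 to 489.5 ± 609.8 CPM, with log2 fold changes of 7.92 and 7.62 that were 6.67 and 6.47 without OC sedentary replicate 5 and 8.65 and 8.43 without sedentary vehicle replicate 5. Mup21 rose 15.0-fold, and C6, a terminal complement component, rose 5.33-fold. Of 17 tested female-biased genes 13 fell, 0 rose and 4 did not pass (15 fell when adjusted over the list alone). Camera with a preset correlation gave adjusted p = 2.11e-17 for the male-biased list and 3.28e-11 for the female-biased list, and for both adjusted p = 0.0868 with an estimated correlation. In sedentary mice 16 of 35 lists were called in all, and 12 of 100 random regroupings of the libraries gave as many. The regroupings kept part of the diet difference, so this share is no clean measure of chance. Of 13 genes of steroid receptors and steroid metabolism 3 rose and 3 fell, as they did over the list alone (camera adjusted p = 0.780). Srd5a1 (steroid 5-alpha-reductase) and Hsd17b2 (which oxidises oestradiol) rose 4.01-fold and 2.59-fold, and Hsd17b6 and Hsd17b13 fell 4.54-fold and 2.20-fold.

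Of 35 nuclear genes of respiratory complex I 13 fell on OC in sedentary mice and 22 did not pass, with a list median of -0.31 and 24 falling when adjusted over the list alone. Ndufa5 fell from 91.5 ± 14.9 to 61.7 ± 6.56 CPM and Ndufa9 from 159.9 ± 22.6 to 124.0 ± 6.28 CPM. Of 15 tested genes of complexes II to V, from 38 in the list, 9 fell (14 when adjusted over the list alone), among them Uqcrc2, 1.37-fold lower, and Uqcrb, with a log2 fold change of -0.58. The untested members included Sdha, Sdhb, Sdhc and Sdhd of complex II and Atp5b of complex V, whose lines were displaced. The camera calls for these lists (adjusted p = 2.38e-10 and 5.09e-07) were lost with an estimated correlation, at adjusted p = 0.426 and adjusted p = 0.405. Sedentary vehicle replicate 5 lay above the other 4 libraries of its group, with a mean log2 CPM of 7.38 against 6.94 to 7.05 for complex I and likewise for complexes II to V, where the other 4 lay at 8.02 to 8.06. Without that library both camera calls with the preset correlation stayed, as did the calls of Ndufa5 (log2 fold change -0.47), Ndufa9, Uqcrc2 and Uqcrb. In the mitochondrial ribosome list 3 of 39 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.14, camera adjusted p = 0.0180 for lower, and adjusted p = 0.817 with an estimated correlation). That call was lost without sedentary vehicle replicate 5 (adjusted p = 0.125), without OC sedentary replicate 3 (adjusted p = 0.192) and with library totals alone (adjusted p = 0.0665). Nnt, the mitochondrial transhydrogenase that supplies NADPH, fell 1.32-fold (adjusted p = 0.00924), and Gpx1, a glutathione peroxidase, fell 1.34-fold (adjusted p = 0.0266). With library totals as the only scaling neither passed, at adjusted p = 0.0593 and adjusted p = 0.0823. The Gpx1 call was also lost without sedentary vehicle replicate 4 (adjusted p = 0.0633) and without OC sedentary replicates 1, 2 and 3 (adjusted p = 0.0694, 0.0512 and 0.0587).

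Of 22 tested genes of fatty acid oxidation and PPARA targets 10 fell and 0 rose (10 and 0 when adjusted over the list alone), among them the thioesterase Acot4 (2.35-fold) and the thiolase Acaa1b (1.87-fold). The list had camera adjusted p = 0.000593, and adjusted p = 0.563 with an estimated correlation. Of 24 cholesterol genes 4 rose and 0 fell (4 and 0 over the list alone), with Nsdhl from 44.5 ± 18.9 to 112.5 ± 14.1 CPM (list adjusted p = 0.00377, and adjusted p = 0.774 with an estimated correlation). Of 19 genes of the unfolded protein response 7 rose (10 over the list alone), including the sensor Ern1 (2.05-fold) and its target Xbp1 (1.40-fold), with list adjusted p = 2.92e-05, and adjusted p = 0.426 with an estimated correlation. Of 12 stellate cell and fibroblast genes 11 fell (11 over the list alone), with Lrat 2.18-fold lower and Cygb at log2 fold change -0.72, which was -0.46 without sedentary vehicle replicate 2 (list adjusted p = 7.90e-06, and adjusted p = 0.405 with an estimated correlation). The B-cell gene Cd79a fell 2.60-fold within a lymphocyte and neutrophil list of which 5 of 15 fell (6 over the list alone; adjusted p = 0.00858, and adjusted p = 0.405 with an estimated correlation). In sedentary vehicle replicate 2 the mean log2 CPM of the stellate list was 5.87 and of the lymphocyte list 1.14, against 4.99 to 5.36 and 0.82 to 1.00 in the other 4 libraries of its group.

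The second comparison asked what the contraceptive diet did in running mice. Rgs7bp rose from 1.49 ± 0.517 to 118.2 ± 45.5 CPM (SD, n = 5; log2 fold change 6.29, SE 0.33; edgeR quasi-likelihood adjusted p = 8.27e-11). Mup20, a male-biased urinary pheromone protein, rose from 43.9 ± 25.2 to 8917 ± 3624 CPM (203.1-fold, adjusted p = 8.50e-07). Prtn3, the protease proteinase 3, rose from 0.167 ± 0.132 to 94.7 ± 55.2 CPM, and Isyna1, the enzyme of myo-inositol synthesis, from 5.94 ± 0.817 to 126.4 ± 32.2 CPM. A total of 1343 genes (13.2% of those tested) changed, 724 higher and 619 lower, and 346 changed more than 2-fold. The count was 817 without OC running replicate 1 and 835 without OC running replicate 3. Scaled by library totals alone, 1390 rose and 335 fell (80.6% higher, against 53.9%), and the median of all genes lay at 0.12.

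Epp13 had 0 counts in running vehicle mice and 757 on OC, at least 252.8-fold higher, and Obp2a and Asic2 were at least 110.2-fold and 109.2-fold higher. Mup1 had 1 count on vehicle and 363 on OC (ratio 363.6, 95% counting interval 64.9 to 14401). Its fitted log2 fold change was 7.81, and 6.49 without OC running replicate 3. Without running vehicle replicate 3, which held that count, the vehicle group was at 0 and the fitted value of 9.15 was no measured fold. For Obp2a, with 0 counts on vehicle, the fitted value of 9.02 was no measured fold, and it was 8.27 without OC running replicate 3. Eci3 fell 36.0-fold and Olig1 10.4-fold. Their running OC libraries held only 0 to 0.183 and 0 to 0.442 CPM, so both folds are imprecise. A1bg, a female-biased plasma glycoprotein gene, fell from 57.8 ± 45.4 to 3.50 ± 5.72 CPM (log2 fold change -4.06, and -5.87 without OC running replicate 4). Acss3 and Ces1b fell 3.19-fold and 3.18-fold. In the male-biased list 19 of 27 genes rose and 0 fell (21 rose when adjusted over the list alone). In the female-biased list 14 of 17 fell (15 when adjusted over the list alone). Their camera adjusted p were 1.63e-15 and 2.31e-14, with adjusted p = 0.0849 and adjusted p = 0.0171 with an estimated correlation.

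In running mice 3 of 35 complex I genes fell (2 when adjusted over the list alone), with Ndufv1 1.28-fold and Ndufs1 1.32-fold lower, and the list did not pass (camera adjusted p = 0.558), with a median of 0.01, a mean of -0.00 and a test direction of lower. Of the genes of complexes II to V 1 of 15 fell (1 over the list alone), Uqcrc1, by 1.23-fold (adjusted p = 0.0255), a call lost without running vehicle replicate 1, 3 or 4 (adjusted p = 0.0523, 0.0729 and 0.0641), without OC running replicate 1 or 3 (adjusted p = 0.0709 and 0.0511) and with library totals alone (adjusted p = 0.0932). In the mitochondrial ribosome list 4 of 39 rose (4 over the list alone), with Mrps18a 1.54-fold and Mrps6 1.92-fold higher (list adjusted p = 0.0374, and adjusted p = 0.915 with an estimated correlation). That list call was lost without running vehicle replicate 2 or 3 (adjusted p = 0.0649 and 0.0503) and without OC running replicate 1, 3 or 4 (adjusted p = 0.234, 0.136 and 0.115). Nnt fell 1.41-fold, and Gpx1, at log2 fold change -0.17 (SE 0.13), did not pass. Of fatty acid oxidation and PPARA targets 12 of 22 fell and 1 rose (14 and 1 over the list alone), with Acaa1b 2.27-fold and Hadh 1.54-fold lower (list adjusted p = 3.20e-07, and adjusted p = 0.420 with an estimated correlation). In the fatty acid and triglyceride synthesis list 6 of 22 fell (7 over the list alone), including the desaturase Fads2 from 1945 ± 425.1 to 902.3 ± 151.1 CPM and Pparg from 14.0 ± 1.89 to 8.02 ± 1.18 CPM (list adjusted p = 0.0374, adjusted p = 0.0567 without running vehicle replicate 3, and adjusted p = 0.521 with an estimated correlation).

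Of 5 tested CAR and PXR targets 4 rose in running mice (4 when adjusted over the list alone), among them Ces2a from 195.4 ± 24.4 to 808.0 ± 61.4 CPM and Por, the reductase that serves cytochromes P450, 2.14-fold (list adjusted p = 3.81e-05, and adjusted p = 0.0171 with an estimated correlation). The list holds 33 genes, and Cyp2b9, Cyp2b10 and Cyp3a11 were among those left out as displaced. In sedentary mice 3 of the 5 rose (3 over the list alone). There the list had camera adjusted p = 0.00556, and adjusted p = 0.132 with an estimated correlation. In the unfolded protein response list 11 of 19 rose (14 over the list alone), including Ern1 1.80-fold and Selenos 1.60-fold (list adjusted p = 4.98e-07, and adjusted p = 0.420 with an estimated correlation). In the stellate list 4 of 12 fell (5 over the list alone), with Reln 1.75-fold and Ecm1 1.68-fold lower (list adjusted p = 0.000803, and adjusted p = 0.521 with an estimated correlation). Hal, the periportal histidine ammonia-lyase, fell 1.75-fold within a periportal list in which 5 of 15 fell and 1 rose (7 and 1 over the list alone; adjusted p = 0.00667, and adjusted p = 0.420 with an estimated correlation). Igf1 fell from 818.1 ± 64.9 to 573.8 ± 90.8 CPM (adjusted p = 0.00577), whereas in sedentary mice its log2 fold change was -0.02 (SE 0.12). The interaction for Igf1 was -0.49 (SE 0.16, adjusted p = 0.201), so the difference did not pass in edgeR, while DESeq2 gave adjusted p = 0.0425. Gdf15 rose 3.27-fold (adjusted p = 0.0424), and the call was lost in limma voom (adjusted p = 0.0567). It was also lost without any of the 5 running vehicle libraries (adjusted p = 0.0861, 0.0640, 0.0937, 0.0606 and 0.0819), OC sedentary replicate 1 (0.0510) or OC running replicates 1, 3 and 5 (0.104, 0.0768 and 0.0864).

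**Figure D2:**
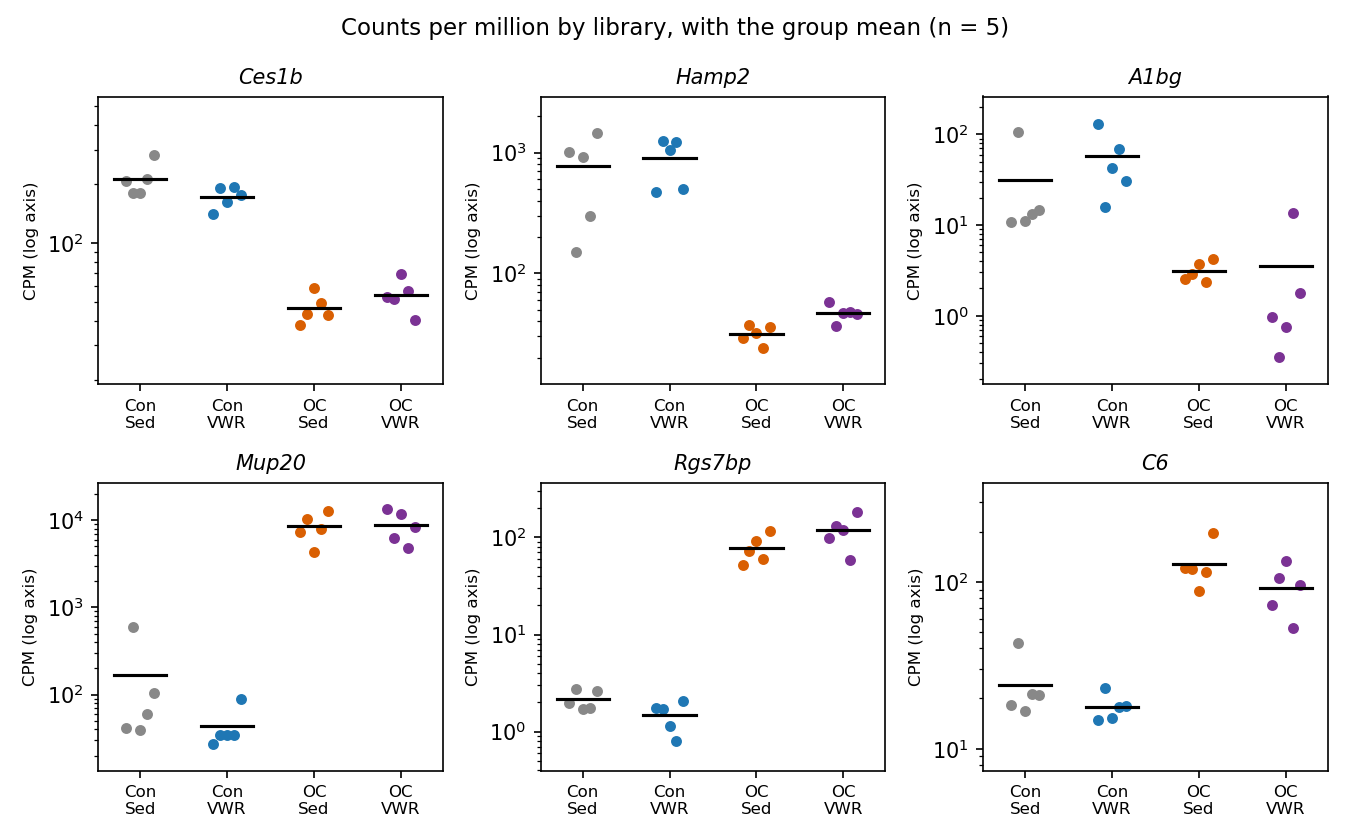
CPM (y axis, log scale) of 6 sex-biased or strongly changed genes in the 4 groups (x axis), with 1 point per mouse and a line at the group mean (n = 5). Every OC library lies below every vehicle library for Ces1b and Hamp2 and above every vehicle library for Mup20, Rgs7bp and C6, while for A1bg 1 running OC library, at 13.7 CPM, lies within the vehicle range.

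Averaged over activity, with 10 OC libraries against 10 vehicle libraries, 1212 genes rose and 1126 fell, 2338 in all (22.9% of those tested). With library totals alone 2559 rose and 599 fell (81.0% higher, against 51.8%), so directions of small changes were relative to the TMM scaling, under which the median of all genes was 0.00. Alb, which encodes serum albumin, fell from 136772 ± 12554 to 80023 ± 8540 CPM in sedentary mice and from 124713 ± 19680 to 72265 ± 13205 CPM in running mice (averaged log2 fold change -0.78, SE 0.10, adjusted p = 8.49e-06). Alb took 10.96% to 14.22% of the counts in vehicle libraries and 6.29% to 9.32% in OC libraries. Leaving out predicted genes without a name, the smallest adjusted p among raised genes were those of Rgs7bp (3.24e-13), Nebl (1.13e-12) and Bmp7 (2.56e-12), and those among lowered genes included Ces1b (3.23e-11) and Hamp2 (4.46e-09).

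In the averaged contrast 21 of 27 male-biased genes rose, including Mup20 (101.5-fold), Mup11 (182.4-fold) and Mup21 (17.7-fold), and 14 of 17 female-biased genes fell, including A1bg (12.9-fold) and Cux2, a female-specific hepatic repressor (2.87-fold). When adjusted over the list alone 21 rose and 15 fell. Of the 21 raised genes 14 were Mup genes, and of the 13 male-biased genes other than these 7 rose, with a median of 0.84 against 2.39 for the whole list. The log2 fold change of Mup20 was 6.67, and 7.39 without sedentary vehicle replicate 2. That of Mup11 was 7.51, and 6.74 without OC running replicate 3. That of A1bg was -3.69, and -3.03 without sedentary vehicle replicate 2 or -4.59 without OC running replicate 4. Of all 35 lists 12 were called. As many were called in 33 of 100 random regroupings of the libraries, though these kept part of the diet difference within each activity group. No regrouping drawn moved either sex-biased list as far. Both lists were called with the preset and with the estimated correlation, at adjusted p = 0.0491 and adjusted p = 0.0290 with an estimated correlation. Many Mup genes are near-identical copies, so single values of Mup genes are uncertain. Those of Ces1b, Ces2a, Hamp2 and Orm1 are also uncertain, because these genes have close relatives. Values of genes that overlap a gene on the other strand are uncertain too, because the sources used here do not say whether counting used strand. Of the growth hormone and IGF list 2 of 18 rose and 5 fell (2 and 7 over the list alone; camera adjusted p = 0.412). Its members Lifr and Stat5a rose 6.29-fold and 3.01-fold, and Igfbp3 and Igf1 fell 1.72-fold and 1.20-fold, the last lost with library totals alone (adjusted p = 0.135). In the list of steroid receptors and steroid metabolism 4 of 13 rose and 4 fell (4 and 5 over the list alone; adjusted p = 0.995). Hsd17b2 and Srd5a1 rose 2.63-fold and 2.67-fold, and Hsd17b6 and Hsd17b13 fell 3.72-fold and 1.90-fold. Esr1, the oestrogen receptor alpha gene, rose 1.27-fold (adjusted p = 0.0330), a call lost without any 1 of 8 libraries, namely sedentary vehicle replicates 2 and 3 (adjusted p = 0.0514 and 0.0568), running vehicle replicates 1 and 2 (0.0647 and 0.0608), OC sedentary replicate 3 (0.0733) and OC running replicates 2, 4 and 5 (0.0572, 0.0506 and 0.0736). The Esr1 call was also lost in limma voom with sample weights (adjusted p = 0.0602). For the growth hormone list the median was -0.11 and the mean 0.01, and for the steroid list the median was 0.00, the mean -0.06 and the test direction higher.

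Averaged over activity, 9 of 35 complex I genes and 7 of 15 genes of complexes II to V fell (10 and 8 when adjusted over the list alone), with Ndufv1 (1.26-fold), Ndufa5 (1.32-fold), Uqcrc1 (1.19-fold) and Cox5a (1.23-fold) among them. The lists had camera adjusted p = 1.66e-05 and 0.000164, and adjusted p = 0.703 and adjusted p = 0.613 with an estimated correlation. Of 26 antioxidant genes 1 rose and 3 fell (1 and 3 over the list alone; adjusted p = 0.663): Gpx3 rose 1.49-fold, while Nnt, Txnrd2 and Gpx1 fell 1.36-fold, 1.20-fold and 1.23-fold, and Cat, at log2 fold change -0.08 (SE 0.09), did not pass. With library totals alone Uqcrc1, Txnrd2 and Gpx1 did not pass (adjusted p = 0.0598, 0.0719 and 0.112). Of 22 fatty acid oxidation and PPARA targets 13 fell and 2 rose (14 and 2 over the list alone), with Acaa1b 2.06-fold, Acot4 2.47-fold and the hepatokine Fgf21 3.03-fold lower (list adjusted p = 8.41e-07, and adjusted p = 0.363 with an estimated correlation). Ppara itself fell 1.45-fold (adjusted p = 0.00534). Of the CAR and PXR targets 4 of 5 rose (4 over the list alone), with Ces2a 3.78-fold and Por 2.01-fold higher (list adjusted p = 0.000164, and adjusted p = 0.0340 with an estimated correlation). Of 19 genes of the unfolded protein response 16 rose and 0 fell (17 and 0 over the list alone), with Ern1 1.92-fold and Xbp1 1.36-fold higher (list adjusted p = 7.74e-08, and adjusted p = 0.328 with an estimated correlation).

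Among oestrogen-sensitive secreted hepatic proteins 11 of 26 fell and 3 rose (12 and 3 when adjusted over the list alone), with the iron hormone gene Hamp 2.40-fold lower, Apoa4 at log2 fold change -2.22 (-1.46 without sedentary vehicle replicate 2), and haptoglobin (Hp) 1.45-fold and Lrg1 1.76-fold higher (list adjusted p = 0.00343, and adjusted p = 0.367 with an estimated correlation). Of 20 hepatokine genes 8 fell and 2 rose (10 and 4 over the list alone), with Enho 2.04-fold lower and Gdf15 2.53-fold and Orm1 1.69-fold higher (list adjusted p = 0.0378, and adjusted p = 0.238 with an estimated correlation). That list call was lost without sedentary vehicle replicate 4, running vehicle replicate 1, OC sedentary replicates 1 and 3 or OC running replicate 5 (adjusted p = 0.0606, 0.0509, 0.0517, 0.0707 and 0.0724). In the periportal list 6 of 15 fell and 1, Mup3, rose, as they did over the list alone (from 3501.6 ± 1814.5 to 7060.5 ± 2726.4 CPM in sedentary mice; list adjusted p = 0.00767, and adjusted p = 0.363 with an estimated correlation). In the stellate list 10 of 12 fell (11 over the list alone), with Reln 1.63-fold and Ecm1 1.55-fold lower (adjusted p = 3.43e-06, and adjusted p = 0.338 with an estimated correlation). Of 16 immediate early genes 4 fell and 1 rose (8 and 2 over the list alone), with Klf6 1.75-fold and Fos 3.02-fold lower and Myc 4.31-fold higher (adjusted p = 0.0378, and adjusted p = 0.703 with an estimated correlation). The immediate early call was lost without sedentary vehicle replicate 4, OC sedentary replicates 1 and 4 or OC running replicate 4 (adjusted p = 0.0631, 0.0575, 0.0785 and 0.0662). Scd1, at -0.99 (SE 0.37), had adjusted p = 0.0606 by edgeR and 0.0254 by DESeq2. By edgeR it passed without sedentary vehicle replicate 2 or 4 (adjusted p = 0.0499 and 0.0145), running vehicle replicate 1 or 5 (0.0263 and 0.0436), OC sedentary replicate 1 (0.0438) or OC running replicate 4 (0.0484). Among the rest of the fixed panel Fasn (0.36, SE 0.39), Srebf1 (-0.19, SE 0.27), F12 (0.03, SE 0.07), Angptl4 (-0.13, SE 0.19) and Igfbp1 (-0.07, SE 0.27) did not pass in the averaged contrast.

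The lists that camera did not call in the averaged OC contrast still held called genes. Of all tested genes 22.9% were called in this contrast, so called members alone do not set a list apart. Fry, which asks whether a list's genes change in either direction, called 29 of all 35 lists in this contrast. It does not compare a list with the other genes. Of 22 genes of fatty acid and triglyceride synthesis 2 rose and 7 fell (adjusted p = 0.177), and of 24 cholesterol genes 4 rose and 0 fell (0.301). Of 6 bile acid genes 0 rose and 2 fell (0.322), and of 21 genes of gluconeogenesis and glycolysis 2 rose and 4 fell (0.732). The mitochondrial ribosome had 4 of 39 higher and 2 lower (0.894), mitochondrial biogenesis and mitophagy 2 of 15 higher and 2 lower (0.691), and NRF2 targets 0 of 10 higher and 1 lower (0.884). Coagulation had 3 of 22 higher and 3 lower (0.332), complement 5 of 17 higher and 2 lower (0.322), acute phase and inflammation 3 of 22 higher and 6 lower (0.663), and interferon response 3 of 27 higher and 3 lower (0.456). Heat shock and chaperones had 2 of 16 higher and 1 lower (0.412), the integrated stress response 3 of 16 higher and 4 lower (0.400), the circadian clock 0 of 16 higher and 3 lower (0.105), and the cell cycle 0 of 27 higher and 8 lower (0.0553). For the cell cycle list the mean log2 CPM of sedentary vehicle replicate 2 was 3.69, against 1.34 to 1.72 in its group. Running vehicle replicate 4 was at 2.66, against 1.45 to 1.64 in its group. Of cell type lists, pericentral hepatocyte genes had 0 of 11 higher and 2 lower (0.663), Kupffer cells and macrophages 1 of 15 higher (0.277), lymphocytes and neutrophils 4 of 15 lower (0.270), liver endothelial cells 2 of 18 lower (0.0543) and cholangiocytes 2 of 14 lower (0.177). When adjusted over the list alone, 3 genes rose and 10 fell in fatty acid and triglyceride synthesis, and 8 rose and 7 fell in acute phase and inflammation. In the mitochondrial ribosome and cholesterol lists 3 rose, in NRF2 targets 0 fell, and in the circadian clock, endothelial and cholangiocyte lists 1 fell. The other counts were the same.

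**Figure D3:**
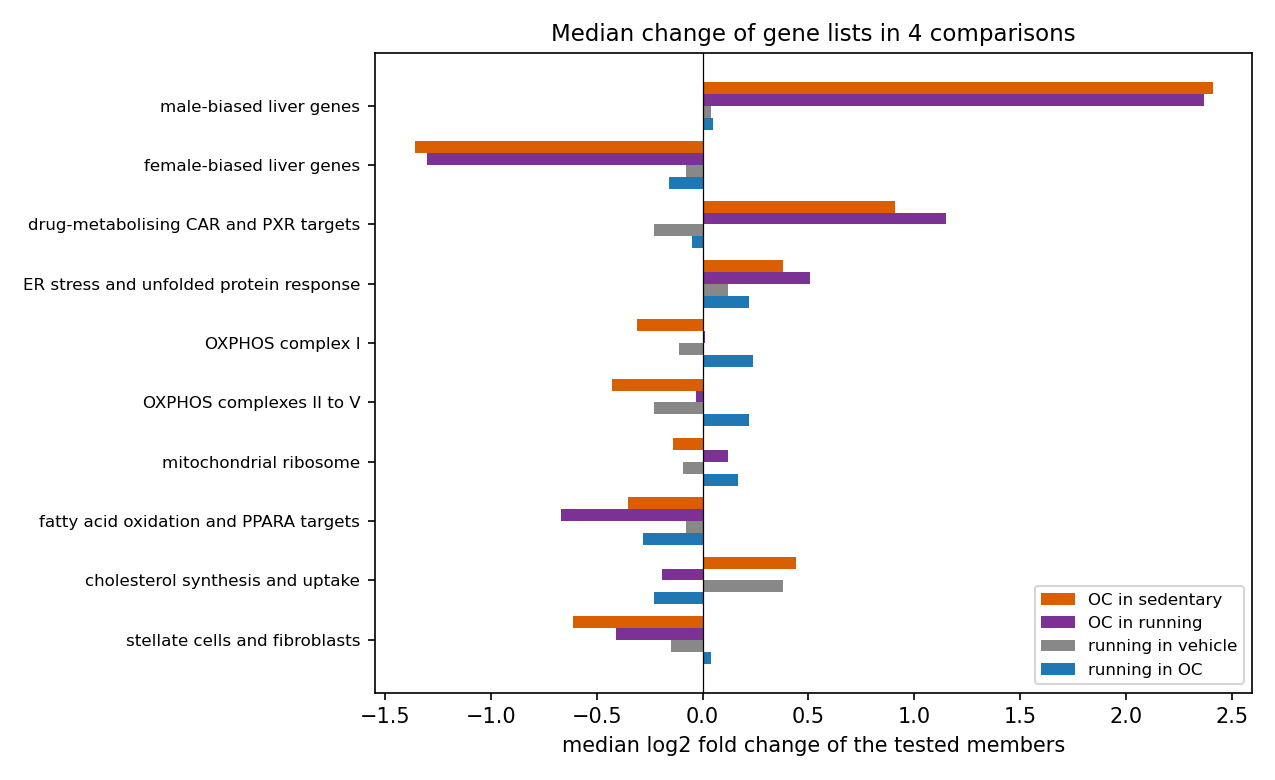
Median log2 fold change (x axis) of the tested members of 10 gene lists (y axis) in 4 comparisons, drawn as bars from 0. Male-biased genes lie above 2 in both OC comparisons and female-biased genes below -1, while the 2 running comparisons lie between -0.16 and 0.05 for these lists.

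The OC effects of sedentary and running mice, which share no library, were correlated across the 10207 genes (Pearson 0.77, Spearman 0.41; genes are not independent replicates). With no filter on low counts Pearson was 0.29. In both comparisons 339 genes were higher and 256 lower, against 66 and 45 for independent lists of these sizes, and 3 genes were called in opposite directions. Of the 1665 genes called in sedentary mice 86.6% had the same sign in running mice. The interaction test, which asks directly whether the OC effect differed with running, called 0 of 10207 genes by edgeR (smallest adjusted p 0.0995; 1802 genes at an unadjusted p under 0.05, against 510 by chance). DESeq2 called 119 genes, limma voom 0 and limma voom with sample weights 4, so the tools differed. By camera 6 of 35 lists were called: complex I (list median 0.34, adjusted p = 1.01e-07), complexes II to V (0.46, adjusted p = 0.000102), the mitochondrial ribosome (0.27, adjusted p = 3.61e-06) and lymphocytes and neutrophils (0.68, adjusted p = 0.00240) were higher. The cholesterol genes (-0.53, adjusted p = 4.54e-05) and pericentral genes (-0.37, adjusted p = 0.0464) were lower. All 6 had adjusted p = 0.928 with an estimated correlation, and in each of these lists 0 genes passed over all genes. When adjusted over the list alone 2 cholesterol genes and 1 pericentral gene were lower, 1 gene of the lymphocyte list was higher, and 0 passed in the other 3. The pericentral call was also lost without sedentary vehicle replicate 2 (adjusted p = 0.300) and without running vehicle replicate 1 or 4 (0.0964 and 0.0583), OC sedentary replicate 2, 3 or 4 (0.0708, 0.0669 and 0.0577) or OC running replicate 1, 2 or 4 (0.0722, 0.0925 and 0.0572).

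**Figure D4:**
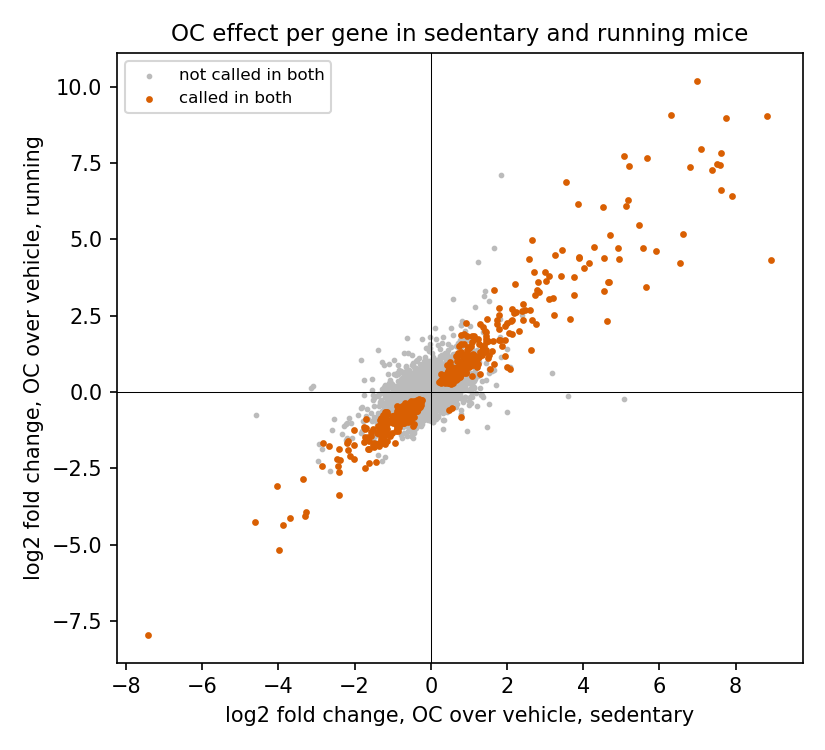
Log2 fold change of OC over vehicle for each of 10207 genes in sedentary mice (x axis) and in running mice (y axis); coloured points were called in both. The points called in both lie in the upper right and lower left quadrants apart from 3 genes, and the correlation across genes was 0.77 (0.29 with no filter on low counts).

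Wheel running changed no gene past the threshold in the edgeR test. In vehicle mice 0 genes were called (1414 at an unadjusted p under 0.05, smallest adjusted p 0.128), with 42 by DESeq2 and 0 by limma voom with or without sample weights. In OC mice 0 were called (694 at an unadjusted p under 0.05), with 1 by DESeq2 and 0 by limma voom with or without weights. Averaged over diet 0 were called (496 at an unadjusted p under 0.05, against 510 by chance), with 2 by DESeq2 and 0 by both forms of limma voom. The averaged OC and averaged running effects had Pearson 0.21 and Spearman 0.27 across genes, and 16 of 100 random regroupings gave a Pearson value as large. Pearson was 0.11 with no filter, 0.13 without the 3 libraries with muscle transcripts, 0.13 without running vehicle replicate 5, 0.11 when the genes moved by 1 place were put back and that library was left out, and 0.14 without OC running replicate 3. The test had found 80.6% of simulated 2-fold changes and 55.3% of simulated 1.5-fold changes for running in vehicle mice.

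Metabolic genes of the panel in running against sedentary vehicle mice were Fasn at log2 fold change 0.83 (SE 0.56), Scd1 at 0.73 (SE 0.52), Igfbp1 at -0.55 (SE 0.38), Fgf21 at -0.54 (SE 0.42) and Gdf15 at -0.36 (SE 0.54), none past the threshold. In OC mice the values were -0.23 (SE 0.56) for Fasn, -0.33 (SE 0.52) for Scd1, 0.54 (SE 0.38) for Igfbp1, -0.27 (SE 0.48) for Fgf21 and 0.38 (SE 0.53) for Gdf15. Averaged over diet, Nnt was at -0.10 (SE 0.07), Gpx1 at 0.04 (SE 0.09), Cat at 0.01 (SE 0.09), Ppara at -0.05 (SE 0.13), Angptl4 at -0.12 (SE 0.19) and Igf1 at -0.03 (SE 0.08).

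Gene lists were called by camera for running although no single gene was. Random regroupings of the same libraries gave as many called lists in 37 of 100 cases for running in vehicle mice, 69 of 100 in OC mice and 52 of 100 averaged over diet. In vehicle mice 12 of 35 lists were called, among them cholesterol genes (median 0.38, adjusted p = 0.000621), lymphocytes and neutrophils (-0.52, adjusted p = 0.000704) and complex I (-0.11, adjusted p = 0.0186), with adjusted p = 0.869, adjusted p = 0.774 and adjusted p = 0.869 with an estimated correlation. The complex I call was lost without sedentary vehicle replicate 5 (adjusted p = 0.659) and without running vehicle replicate 1 (adjusted p = 0.0648). The mitochondrial ribosome was lower in vehicle mice (-0.09, adjusted p = 0.0483, and adjusted p = 0.869 with an estimated correlation). That call was lost with DESeq2 size factors (adjusted p = 0.0507) and without sedentary vehicle replicate 2, 4 or 5 (0.0917, 0.0976 and 0.586), running vehicle replicate 2, 3 or 5 (0.128, 0.0919 and 0.0590), OC sedentary replicate 1 or 4 (0.0510 and 0.0545) or OC running replicate 4 (0.0512). In OC mice 8 lists were called, with higher medians for complex I (0.24, adjusted p = 3.60e-11), the mitochondrial ribosome (0.17, adjusted p = 1.27e-09) and the unfolded protein response (0.22, adjusted p = 2.55e-05) and a lower one for fatty acid oxidation (-0.28, adjusted p = 6.50e-05), all at adjusted p = 0.840 with an estimated correlation. Cholesterol genes, higher with running in vehicle mice, were lower in OC mice (-0.23, adjusted p = 0.00631, and adjusted p = 0.862 with an estimated correlation), a call lost without OC sedentary replicate 2 (adjusted p = 0.154) and without OC running replicate 2 (adjusted p = 0.730). Averaged over diet 10 lists were called, including the unfolded protein response (0.17, adjusted p = 2.28e-09), the interferon response (-0.19, adjusted p = 8.63e-05), fatty acid oxidation (-0.15, adjusted p = 8.63e-05) and Kupffer cells and macrophages (-0.21, adjusted p = 0.000586), all at adjusted p = 0.839 with an estimated correlation. For Kupffer cells and macrophages the median was -0.26 in vehicle mice and -0.05 in OC mice. Sedentary vehicle replicate 2 had a mean log2 CPM of 5.15 for that list against 4.37 to 4.67 in its group, and without it the averaged call stayed. In the lists named here 0 genes passed when adjusted over the list alone, apart from 1 raised gene of the unfolded protein response in OC mice. Fry called 0 of the 35 lists in each running comparison and in the interaction, for a change in 1 direction and for a change in either.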

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

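Of the tests in this part, those of scaling and of male animals for the sex-biased genes, those of mixing and of other liver cells for sedentary vehicle replicate 2, and that of single libraries for complex I were chosen only after the result was seen, as was the comparison of single lists with random regroupings.

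In 24 of 351 group values 1 library stood apart from the other 4 by Dixon's test, where chance sets apart about 5% (18 values). Groups with at most 3 counts were left out of this screen after a first version of it. Sedentary vehicle replicate 2 accounted for 9 of the 24. Its score on the second principal component was 53.0 against -3.1 to 0.1 in its group. In log2 CPM it had C6 at 5.42 (others 4.09 to 4.42), Lrat at 5.91 (5.27 to 5.42), Isyna1 at 3.57 (2.40 to 2.65), A1bg at 6.74 (3.47 to 3.89), Ndufs1 at 6.86 (7.09 to 7.14), Ces2a at 6.64 (7.73 to 8.08), Apoa4 at 12.22 (8.33 to 9.18) and Igfbp3 at 5.24 (4.26 to 4.53). In sedentary vehicle replicate 5 Ndufa5 was at 6.88 (6.36 to 6.45) and Acaa1b at 10.14 (10.77 to 10.88). Running vehicle replicate 2 had Krt4 at 2.64 (-2.78 to -2.15). Running vehicle replicate 5 had Mup20 at 6.47 (4.76 to 5.13) and Por at 10.56 (9.82 to 9.95). OC sedentary replicate 1 had Igfbp1 at 6.86 (8.25 to 8.48). In OC sedentary replicate 3 Nebl was at 4.28 (3.46 to 3.68) and Esr1 at 7.29 (6.82 to 6.87). In OC sedentary replicate 4 Lrat was at 5.04 (3.99 to 4.28) and Stat5a at 4.89 (5.79 to 5.93). OC sedentary replicate 5 had Hsd17b6 at 5.07 (7.06 to 7.75). OC running replicate 1 had Lrat at 5.38 (3.88 to 4.18). In OC running replicate 3 Srd5a1 was at 6.28 (5.77 to 5.89) and Hamp at 9.29 (8.70 to 8.80). OC running replicate 5 had Fgf21 at 0.74 (1.71 to 2.10).

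What set sedentary vehicle replicate 2 apart was weighed against 3 technical explanations, and no biological one was tested. Mixing with RNA of a sedentary OC library as the only cause was argued against by 165 genes more than 2-fold above all other 9 sedentary libraries (0 to 15 such genes in each of the others), since a mix lies between its sources. A first test, the share of OC RNA needed by lowered minus that by raised genes, gave 38.6 percentage points against 20.5 to 57.9 in the other 4 libraries and decided nothing. By raised genes alone the share was 6.3% (bootstrap interval 2.2 to 16.2), against -0.9 to 2.3 in the other 4. Krt4, Epp13, Obp2a and Asic2, at 0 CPM in this library, gave no sign of OC RNA. A small admixture beside another cause was thus not excluded. Low depth was argued against by a gap over range of 0.95 on the second component after thinning to the lowest total. A larger share of other liver cells stays open, because 4 of 5 cell type lists lay above the other libraries (macrophages by 0.67, cholangiocytes by 0.69, stellate cells by 0.66 and lymphocytes by 0.19 on the log2 scale) while endothelial cells, at 0.05, did not. The cell cycle list, at a mean log2 CPM of 3.69 against 1.34 to 1.72 in its group, was not part of these tests.

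By camera with the preset correlation the sex-biased lists moved apart with OC in both activity groups, but with an estimated correlation only the female-biased list in running mice was called (adjusted p = 0.0171), not the male-biased list there (adjusted p = 0.0849) or either list in sedentary mice (adjusted p = 0.0868 for both). An error of scaling moves all genes alike and cannot by itself set lists apart. It was argued against by the gap of 3.65 between the medians of the male-biased and female-biased lists (bootstrap SE 1.09). That gap restates the pattern, and its SE treats genes, related Mup copies included, as independent. Reads shared among Mup genes did not account for the whole pattern, since the 13 male-biased genes without them had a camera adjusted p = 0.000164, although adjusted p = 0.155 with an estimated correlation, with 7 rising and a median of 0.84 against 2.39 for the whole list. Male animals in the OC groups were argued against by Xist, at 763.8 CPM or more in every OC library. As a hypothesis found and tested on the same data, the contraceptive diet may shift the liver from a female towards a male pattern of expression.

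By the interaction test 6 lists differed between activity groups in their OC effect: complex I (camera adjusted p = 1.01e-07), complexes II to V (0.000102), the mitochondrial ribosome (3.61e-06), cholesterol synthesis and uptake (4.54e-05), pericentral hepatocyte genes (0.0464) and lymphocytes and neutrophils (0.00240), all at adjusted p = 0.928 with an estimated correlation. For complex I the median interaction of 0.34 lay at percentile 99.6 of lists matched on expression and exon length. Those lists drew genes independently and so lack any correlation within complex I. The percentile therefore cannot exclude short transcripts as the explanation. The matched lists had a median of 0.18, so part of the shift was shared by such genes. Leaving out 1 library did not lose its camera call with the preset correlation (highest adjusted p = 5.89e-06, without sedentary vehicle replicate 5). That test called as many lists in 94 of 100 regroupings, so the influence of that library was not excluded. Chance was not excluded, because 9 of 100 regroupings of the libraries gave a median as far from 0 (highest other -0.40). No biological explanation is therefore offered.

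Of the 570 genes moved by 1 place, which the comparisons do not use, 140 (24.6%) changed with OC averaged over activity when moved back, 71 higher and 69 lower, against 20.6% of the other genes in that fit. They included Serpina1e (log2 fold change 4.26), Grid1 (-3.32) and Abcc3 (1.47), named after their values were seen. These values rest on the assumption of a move by 1 place and lack running vehicle replicate 5. Serpina1e has near-identical copies.

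Random regroupings of the libraries, 100 per comparison with the real one included, tested each count. For OC in sedentary mice 1 of 100 (the real one) gave as many genes, with 1665 against at most 250. For OC in running mice it was 1 of 100, with 1343 against at most 5, and for the averaged contrast 1 of 100, with 2338 against at most 52, so chance was excluded for these. For running in vehicle mice, running in OC mice, running averaged over diet and the interaction, with 0 genes each, 100 of 100 gave as many, with at most 36, 3, 2 and 21 genes. A count of 0 fixes that outcome in advance, so it decides nothing for these. The correlation of the OC effects, 0.77, was reached by 1 of 100, the real one (highest other -0.72). Values were compared without their sign. Reversing the diets in only 1 activity group, which was not drawn, would give as large a value with the opposite sign. The share thus depends on the regroupings drawn and does not by itself exclude chance. The correlation of the averaged OC and running effects, 0.21, was reached by 16 of 100 (highest other 0.33), so chance was not excluded.

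Chance was not excluded for the number of lists called by camera in any comparison. For the OC comparisons this decides little. Within an activity group 5 OC and 5 vehicle libraries cannot be divided evenly into groups of 5, so regroupings kept part of the diet difference. As many lists were called in 12 of 100 regroupings for OC in sedentary mice (16 lists, at most 20 in the others) and 50 for OC in running mice (10, at most 20). The numbers were 37 for running in vehicle mice (12, at most 20), 69 for running in OC mice (8, at most 16) and 33 for OC averaged (12, at most 18). They were 52 for running averaged (10, at most 18) and 94 for the interaction (6, at most 18). Single lists were then compared with the regroupings by their mean shift from all genes. Fewer than 5 of 100 gave as large a shift for 13 lists with OC in sedentary mice, 13 in running mice and 12 averaged, but for 2, 1 and 0 lists with running in vehicle mice, in OC mice and averaged, and 1 with the interaction.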

How the results depend on the processing

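The alternatives with undecided genes, moved genes, all lines as they stood and without 3 libraries were chosen only after the data were seen. Counts for the 3 OC contrasts kept their size within 1.5 times under every alternative other than leaving out 1 library, except 2224 for OC in running mice by limma voom with sample weights. Of the 1665, 1343 and 2338 calls, limma voom shared 1517, 1258 and 2218. By DESeq2 the counts of 0 became 42 for running in vehicle mice, 1 in OC mice, 2 averaged over diet and 119 for the interaction, and by limma voom with sample weights the interaction had 4. The cause was not tested.

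The correlation of the OC effects, 0.77, was 0.29 with no filter, 0.80 with sample weights, 0.71 with the moved genes moved back and without running vehicle replicate 5 (0.73 without that library alone), 0.74 with all lines as they stood and 0.73 without the 3 libraries with muscle transcripts. That of the averaged effects, 0.21, was 0.11 with no filter, 0.11 with the moved genes and without that library (0.13 without it alone) and 0.13 without those 3 libraries. The cause was not tested. Over all contrasts 74 list calls became 5 with an estimated correlation and 29 by fry in 1 direction, and fry in either direction gave 78. The first allows for correlated genes, and fry asks another question.

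Leaving out 1 library gave 998 (without OC sedentary replicate 1) to 1794 genes for OC in sedentary mice, 817 (without OC running replicate 1) to 1679 in running mice and 2043 to 2616 averaged. Running gave 0 in vehicle mice each time, 0 to 1 in OC mice and 0 to 1 averaged, and the interaction 0 to 2. The correlations ran from 0.72 to 0.78 and from 0.13 to 0.28, and list calls from 66 to 89. Without sedentary vehicle replicate 2 the OC counts were 1629 (1326 of the 1665 shared), 1658 (1343 shared) and 2616 (2202 of the 2338 shared).

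For 170 named gene results, 4521 of 4577 values kept direction and side of the threshold, 48 were weaker, 8 stronger and 0 reversed. Of these results 127 were called, mostly for genes chosen by large or clear changes in these same data. Most alternatives left out only 1 library. This stability was therefore largely built in and says little about calls of other genes. For 56 list results, 1263 of 1400 values did, 133 were weaker, 4 stronger and 0 reversed. DESeq2 gave no adjusted p for some genes, Mmp12 among them, which have no value there. No paired analysis was possible because replicate numbers carry no pairing. Pseudocounts were not varied, because the values used are whole numbers taken to be counts. At this depth 29 of 58 simulated 1.5-fold changes were recovered for OC in sedentary mice.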

Other observations

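The genes Mb, Pnliprp1, Xist and Kdm5d were chosen after their values were seen, and the comparison of single lists with random regroupings was a test added after other results were seen. Heat shock and chaperone genes in running against sedentary vehicle mice had a mean shift from all genes of 0.24 on the log2 scale, with 11 of 16 members above 0. Of 100 regroupings 1, the real one, gave as large a shift (highest other 0.22). Lymphocyte and neutrophil genes in that comparison had a shift of -0.49, with 14 of 15 members below 0, and 1 of 100, the real one, gave as large a shift (highest other 0.47). Sedentary vehicle replicate 2 had a mean log2 CPM of 1.14 for that list, above the 0.82 to 1.00 of its group. The bile acid genes in running against sedentary OC mice had a shift of -0.13, with 5 of 6 members below 0, and 2 of 100 regroupings gave as large a shift. No member of these lists passed the threshold in these comparisons. With 35 lists in each comparison, chance alone gives 1 or 2 lists that fewer than 5 of 100 regroupings match.

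Myoglobin (Mb), a muscle transcript, had 147 to 447 counts in 3 libraries (running vehicle replicate 2, OC sedentary replicate 3 and OC running replicate 5) and at most 7 in the other 17. The pancreatic lipase relative Pnliprp1 had 64 counts in running vehicle replicate 5, at most 1 in the other 9 vehicle libraries and 3 to 21 in OC libraries. Mmp12, a macrophage metalloproteinase, had 657 counts in sedentary vehicle replicate 2 and 2 to 24 in the rest of its group. Xist had 10249 to 27799 counts in all 20 libraries, and the Y-linked gene Kdm5d had 2 counts in 1 library and 0 in the others.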
